A study of Homo sapiens with 15 samples.

How the data were processed

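RNA sequencing of MelJuSo, a human melanoma cell line, was analysed in 15 libraries, 3 replicates (A, B and C) from each of 5 cell lines derived from it. Per the labels, 4 of the lines carry dCas12a, a nuclease-dead Cas12a that binds DNA where a guide RNA directs it, fused to the activation domain VP64 and to a 5xALFA tag. A nanobody against the tag brings a further activation domain, VP64 in one pair of lines and p65, which is part of the RELA protein, in the other pair. In each pair, one line also holds a guide cassette aimed at CD4 and the other holds none. The remaining line has tagged dCas12a without VP64, the nanobody alone and no guides, and is called the line without an activation domain. The labels describe total RNA from cells grown to confluency, with extraction, library preparation and sequencing by a service provider. They do not say whether replicates A, B and C were separate cultures or aliquots of one, so the replicates may be technical and p-values measure only the spread between these samples.

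The deposited expected counts are reads per gene estimated by RSEM after alignment with STAR to hg38, per the labels and the file headers. TPM values were deposited in the same tables and are, per the file headers, RSEM's length-scaled transcript abundances from the expected counts and effective lengths. The deposited effective lengths (another unit, in bases) are, per the file headers, RSEM's mean effective transcript length of each gene, used here only for an alternative. Versions, settings and strandedness are not given in the sources used here. Each library has its own table of 58813 entries. Of these, 58721 gene identifiers matched release 29 of the GENCODE annotation of hg38, and 58252 of them have a current symbol. The other 92 entries are spike-in sequences with 0 to 7 counts per library, at most 3.65e-05% of a library, and were left out. Expected counts summed to between 15643705 and 23072512 per library, which leaves rare genes at few counts and wide intervals.

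Expected counts were rounded to whole numbers and fitted in edgeR 4.0.16 under R 4.3.3 by quasi-likelihood, with 1 coefficient per line over all 15 libraries and TMM normalization (factors 0.983 to 1.014). Genes were kept by filterByExpr with a minimum count of 10, which left 14961 genes. The typical biological coefficient of variation was 5.45%. There were 7 comparisons. They were guides against no guides with each nanobody, p65 against VP64 without and with guides, each activation domain against none, and the difference between the guide effects of the p65 and VP64 arms. P-values were adjusted by Benjamini-Hochberg over all genes within a comparison, with a threshold of 0.05, and a second count also asked for a log2 fold change of at least 1 in size. Library-scaled counts (CPM, per 1e6 counts) were computed from rounded counts with TMM factors. Standard errors of log2 fold changes come from the edgeR fit. CD4 was also compared by an exact 2-sided permutation test of TPM, which cannot go below 0.1 with 3 libraries against 3.

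Gene lists were 26 in number, and 25 had at least 5 tested members. They cover genes around CD4, signalling targets, immune and stress responses, cell cycle, melanoma cell states, metabolism, coactivators, markers of other cell types, and mitochondrial and ribosomal genes. One list holds every annotated gene but CD4 itself whose start lies within 500 kb of the start of CD4. The list of T cell markers had 2 tested members and was not tested as a list. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. Camera asks whether a list differs from the other genes. Counts of members past the threshold are given over all genes and, in brackets, adjusted over the list alone.

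Named genes follow a rule. CD4 and RELA are named in every comparison, RELA because its coding sequence supplies the p65 domain. Added to these are up to 10 genes per direction with the largest log2 fold change among those past the threshold, with a mean of at least 1 CPM and with no overlap between the libraries compared. With 3 libraries against 3, chance gives such a separation with a probability of 0.1. Up to 4 members of each list with the smallest p serve as examples. In the difference of guide effects, up to 5 genes per direction are named, and genes without a symbol are skipped. Some genes that meet the rule are not reported here. The samples, comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined.

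The alternatives were DESeq2 size factors in edgeR, no low-count filter, a filter at a mean of 1 CPM, the Wald test of DESeq2 1.42.0, only the libraries compared, the replicate letter as a block, unrounded expected counts, an offset from effective lengths, and leaving out each replicate in turn. Lists were also tested with fry. Correlations were repeated with Spearman's rho, without CD4 and on genes with a mean of at least 10 CPM. Removal of trends on GC content and length, and thinning to the lowest depth, were added after the data had been seen. The replicate letter was not used as a block in the reported fit, since the labels state no shared culture or day. Correlations of residuals between same-letter libraries of different lines ran from -0.073 to 0.064 over 30 pairs, none above 0.1.

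The edgeR fit was tested on simulated data with the real library sizes for the comparison of guides with nanobody-VP64, over 14505 genes. It recovered 73.1% of 67 genes changed 1.5-fold, 88.1% of 67 changed 2-fold and 100% of 66 changed 4-fold. DNA replication genes were also lowered there as a list. In that run 12 unchanged genes were called, 5.77% of all calls, with those on the list included. In the simulated comparison of p65 with VP64 without guides, where nothing was changed, 1 gene was called. The chance agreement of the comparisons that share control libraries was simulated 20 times. Where a gene had 0 counts in one group, a floor of 3 counts over the group gives a lower bound of the fold; floors and counting intervals (95%) cover counting error only. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.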

Results

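Gene expression was measured by sequencing total RNA from 5 lines derived from MelJuSo, a human melanoma cell line, with 3 libraries per line. The lines with the nanobody fused to VP64 or to p65 were present with and without the guides against CD4, and a further line had neither an activation domain nor guides. Expected counts per library summed to between 15643705 (VP64 with guides, replicate A) and 23072512 (no activation domain, replicate C), and 19659 to 20632 genes had a count. Folds are given with SE and n = 3 libraries per group. Adjusted p values are from edgeR unless camera is named.

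CD4, the targeted gene, encodes a co-receptor of T cells (ENSG00000010610.9, hg38, chromosome 12, 6786858 to 6820808). With guides it had 29905, 37603 and 28750 counts in the VP64 line and 38746, 35894 and 39141 in the p65 line (replicates A, B and C). Without guides it had 169, 164 and 176 counts with VP64, 197, 214 and 245 with p65, and 76, 88 and 28 in the line without an activation domain. As TPM, the levels with guides were 924 ± 27.0 for VP64 and 1002 ± 56.1 for p65 (SD, n = 3). Without guides they were 4.24 ± 0.397 for VP64, 5.31 ± 0.382 for p65 and 1.57 ± 0.906 without an activation domain (SD, n = 3). The exact 2-sided permutation test of TPM gave p = 0.1, the smallest it can give, in each pair of lines except p65 against VP64 with guides, where p = 0.2.

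**Figure D1:**
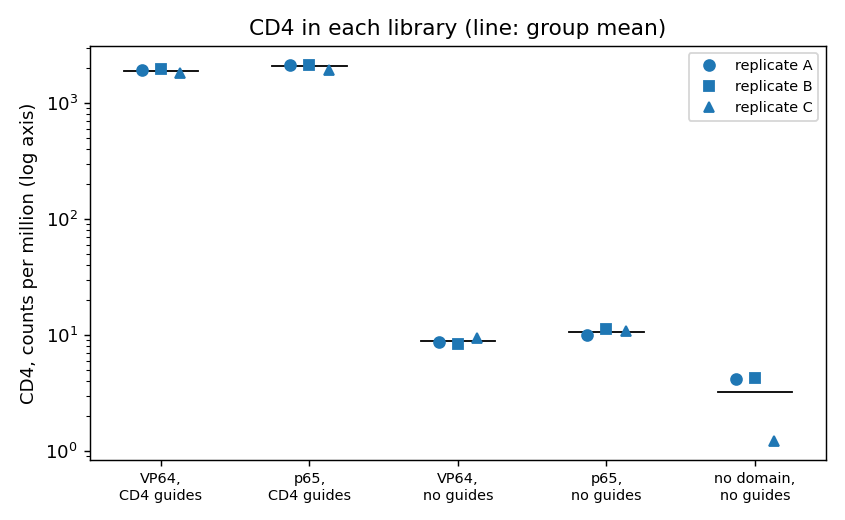
CD4 in each of the 15 libraries, in CPM on a log axis, with the mean of each line. The libraries with guides sit between 1816 and 2131 CPM, and those without guides between 1.22 and 11.1 CPM.

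Guides were compared with no guides in the lines with the nanobody fused to VP64, which asks what the guide cassette changes when VP64 alone is the activation domain. CD4 rose 215-fold by mean CPM, from 8.83 ± 0.541 to 1895 ± 68.7 CPM (SD, n = 3), a log2 fold change of 7.75 (SE 0.146, adjusted p = 2.95e-20). RCN3, an endoplasmic reticulum calcium-binding protein (ENSG00000142552.7, chromosome 19, 49527618 to 49546962), rose from 16.5 ± 1.22 to 204 ± 8.98 CPM (log2 fold change 3.62, SE 0.061, adjusted p = 6.31e-21). OASL, an interferon-induced gene, rose from 2.15 ± 0.0912 to 16.2 ± 1.75 CPM (2.92, SE 0.15, adjusted p = 2.98e-12). ESM1, which encodes a secreted proteoglycan, fell from 50.1 ± 1.78 to 11.5 ± 2.15 CPM (-2.14, SE 0.124, adjusted p = 1.79e-11), and ANGPTL4, an inhibitor of lipoprotein lipase, fell from 59.3 ± 5.56 to 17.6 ± 3.51 CPM (-1.76, SE 0.103, adjusted p = 1.95e-11). Of 14961 genes tested, 2889 rose and 3185 fell, and 353 of those that rose and 106 of those that fell changed at least 2-fold.

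The other genes with the largest rises were SLCO4A1-AS1 (log2 fold change 3.53, SE 0.399), the cholesterol transporter ABCG1 (3.23, SE 0.378), the scavenger receptor SCARA5 (3.17, SE 0.256), the immune receptor LAG3 (2.95, SE 0.425), SSUH2 (2.90, SE 0.200), MYOZ2 (2.55, SE 0.496) and PLEKHS1 (2.54, SE 0.383). Among the largest falls were ABCC9 (-2.22, SE 0.379), GJA5 (-1.91, SE 0.254), RIMS2 (-1.79, SE 0.199), RIMS1 (-1.75, SE 0.387), GALNTL6 (-1.70, SE 0.386) and KRTAP4-8 (-1.60, SE 0.431). RMRP (-5.03, SE 1.152, adjusted p = 0.00125) and RPPH1 (-5.00, SE 1.192, adjusted p = 0.00174), the RNAs of RNase MRP and RNase P, also passed, but RPPH1 ran from 1.07 to 33.8 CPM among the VP64 libraries without guides. RMRP is uncertain, since 2 overlapping annotated genes carry this symbol, and SLCO4A1-AS1 is uncertain because the strandedness is not given in the sources used here. RELA fell slightly (-0.14, SE 0.039, adjusted p = 0.00481).

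Genes next to CD4 were among those that rose. PTMS, which starts at -21.3 kb from the start of CD4 (ENSG00000159335.15, chromosome 12, 6765516 to 6770952), rose by 2.10 on the log2 scale (SE 0.055, adjusted p = 1.73e-17). LAG3 starts at -14.3 kb. MLF2 (0.29, SE 0.041), P3H3 (0.43, SE 0.056) and ENO2 (0.41, SE 0.045) rose less. Of 13 tested members of the CD4 neighbour list, 9 rose and 2 fell (9 and 3 adjusted over the list alone), with a median log2 fold change of 0.41 and camera adjusted p = 0.0013 (adjusted p = 0.102 with an estimated correlation). Of 42 tested genes that start within 500 kb, 20 rose and 6 fell (21 and 6 adjusted over the list alone), among them GAPDH (0.29, SE 0.032) and C1R (0.60, SE 0.072), with camera adjusted p = 0.0013 (adjusted p = 0.102 with an estimated correlation).

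**Figure D2:**
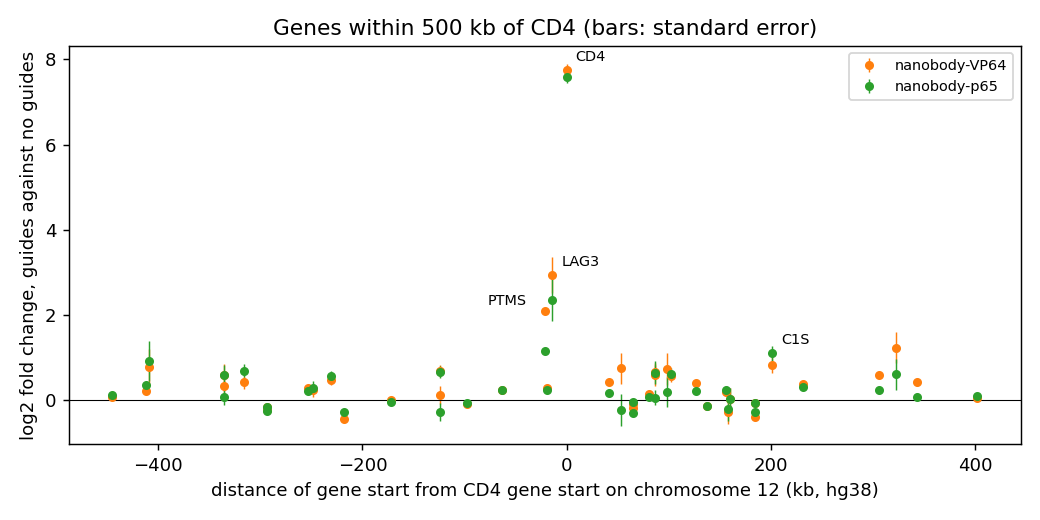
Log2 fold change with guides (vertical axis, with SE) of the tested genes against the distance of their start from that of CD4 in kb (horizontal axis), for both nanobodies. PTMS and LAG3, within 50 kb of CD4, lie at 2.10 and 2.95 with VP64 and at 1.17 and 2.36 with p65.

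In the lists below, counts adjusted over the list alone equal those over all genes where they are not given. Interferon response genes rose in 19 of 24 cases and fell in 0 (20 and 0 adjusted over the list alone), among them IFIT2 (1.70, SE 0.113), IFIT3 (1.53, SE 0.111) and IFI6 (0.93, SE 0.072), with camera adjusted p = 1.44e-09 (adjusted p = 0.0298 with an estimated correlation). MHC class I genes rose in 12 of 15 cases and fell in 1. HLA-B stood at 0.69 (SE 0.049), with camera adjusted p = 8.01e-07 (adjusted p = 0.0983 with an estimated correlation). NF-kB targets rose in 10 of 26 cases and fell in 0. IER3 stood at 0.81 (SE 0.052), NFKB2 at 0.73 (SE 0.050) and TRAF1 at 1.61 (SE 0.115), with camera adjusted p = 0.0016 (adjusted p = 0.0629 with an estimated correlation). Unfolded protein response genes rose in 17 of 18 cases (18 adjusted over the list alone). HSPA5 stood at 0.72 (SE 0.039) and DNAJB9 at 0.92 (SE 0.077), with camera adjusted p = 8.83e-10 (adjusted p = 0.0629 with an estimated correlation). All 23 tested DNA replication genes fell. RRM2 stood at -0.56 (SE 0.045) and CDC6 at -0.53 (SE 0.053), with camera adjusted p = 1.95e-10 (adjusted p = 0.0983 with an estimated correlation). Of 20 G2/M genes 19 fell. MKI67 stood at -0.81 (SE 0.067) and CENPF at -0.67 (SE 0.064), with camera adjusted p = 1.6e-09 (adjusted p = 0.102 with an estimated correlation). YAP/TEAD targets fell in 11 of 17 cases and rose in 1. DLC1 stood at -0.81 (SE 0.052) and CCN2 at -0.96 (SE 0.066), with camera adjusted p = 3.22e-05 (adjusted p = 0.0983 with an estimated correlation).

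Melanocyte lineage genes rose in 10 of 17 cases and fell in 1 (11 and 1 adjusted over the list alone). ERBB3 stood at 1.59 (SE 0.106) and S100B at 1.65 (SE 0.118), with camera adjusted p = 0.0013 (adjusted p = 0.102 with an estimated correlation). MAPK output genes rose in 13 of 17 cases and fell in 2 (14 and 2 adjusted over the list alone). SPRY2 stood at 0.94 (SE 0.056) and PHLDA1 at 0.61 (SE 0.038), with camera adjusted p = 3.22e-05 (adjusted p = 0.102 with an estimated correlation). Immediate-early genes rose in 12 of 18 cases and fell in 2. NR4A1 stood at 1.03 (SE 0.108) and SRF at -0.32 (SE 0.055), with camera adjusted p = 0.00698 (adjusted p = 0.361 with an estimated correlation). Hypoxia and glycolysis genes rose in 11 of 21 cases and fell in 2 (13 and 2 adjusted over the list alone). NDRG1 stood at 0.97 (SE 0.053) and ALDOC at 1.11 (SE 0.066), with camera adjusted p = 0.000238 (adjusted p = 0.0629 with an estimated correlation). Cholesterol synthesis genes rose in 7 of 20 cases and fell in 1. INSIG1 stood at 1.71 (SE 0.085), with camera adjusted p = 0.00354 (adjusted p = 0.0983 with an estimated correlation). P53 targets rose in 13 of 21 cases and fell in 4 (14 and 4 adjusted over the list alone). GDF15 stood at 1.34 (SE 0.075) and AEN at -0.59 (SE 0.040), with camera adjusted p = 0.0121 (adjusted p = 0.103 with an estimated correlation).

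Lists that camera did not pass with VP64 also held changed genes. In the integrated stress response 8 of 21 rose and 4 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.0874), with DDIT4 at 2.10 (SE 0.070) and STC2 at -0.81 (SE 0.053). In the extracellular matrix list 6 of 21 rose and 5 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.232), with SPARC at 0.87 (SE 0.037) and COL6A1 at 0.96 (SE 0.059). Of 39 coactivator genes 1 rose and 10 fell (1 and 9 adjusted over the list alone; camera adjusted p = 0.0731), with CREBBP at -0.34 (SE 0.058). Of 14 heat shock genes 5 rose and 6 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.938), with a median of -0.08 and a mean of 0.26, opposite in sign, and the camera direction was upward. Of 16 genes of dedifferentiated melanoma 6 rose and 7 fell (camera adjusted p = 0.64), with LOXL2 at 0.72 (SE 0.042) and EGFR at -0.70 (SE 0.058), a median of -0.07, a mean of 0.04 and a downward camera direction. Mitochondrially encoded genes fell in 4 of 13 cases (camera adjusted p = 0.106), and ribosomal protein genes rose in 7 and fell in 5 of 32 (camera adjusted p = 0.609). Of 11 myeloid markers 2 rose, including CD68 (0.47, SE 0.056), of 7 epithelial markers 1 rose (CLDN4, 0.86, SE 0.124), and of 6 fibroblast and endothelial markers 1 rose (ACTA2, 0.32, SE 0.062), with camera adjusted p = 0.333, 0.333 and 0.411. The T cell marker IL7R fell (-0.79, SE 0.061) and TRAC did not pass (-0.49, SE 0.438, adjusted p = 0.401).

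RMRP was -3.12 and RPPH1 -2.90 without replicate B of VP64 without guides, ABCG1 was 4.49 without that library, RMRP was -5.70 without replicate B of VP64 with guides, and KRTAP4-8 was -2.44 without replicate A of VP64 with guides. With the effective-length offset LAG3 was 3.66, and the RELA call was lost (-0.12), as it was without replicate B of VP64 without guides (-0.11).

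Guides were next compared with no guides in the lines with the nanobody fused to p65, which asks the same of p65 recruited beside VP64. CD4 rose 194-fold by mean CPM, from 10.6 ± 0.563 to 2063 ± 115 CPM (log2 fold change 7.60, SE 0.143, adjusted p = 2.96e-20). MGAT4C, a glycosyltransferase gene (ENSG00000182050.13, chromosome 12, 85955666 to 86838904), rose from 0.147 ± 0.013 to 22.4 ± 0.973 CPM (7.20, SE 0.238, adjusted p = 1.1e-15). PIGR, the polymeric immunoglobulin receptor, rose from 0.0636 ± 0.0211 to 8.68 ± 1.03 CPM (6.93, SE 0.344, adjusted p = 8.99e-13), and SSUH2 from 0.903 ± 0.116 to 22 ± 2.88 CPM (4.59, SE 0.193, adjusted p = 4.9e-14). ESM1 fell from 54.3 ± 3.28 to 12.9 ± 3.64 CPM (-2.06, SE 0.119, adjusted p = 1.31e-11). Of 14961 genes tested, 2805 rose and 3018 fell, and 329 and 62 of these changed at least 2-fold.

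ESYT3 had 167 counts with guides and 0 without, at least 62-fold higher, and THEG had 135 and 0, at least 50.1-fold higher, with a floor of 3 counts over the group (at least 39.1-fold and 31.6-fold without replicate C of p65 without guides). DNAH9 had 124 counts against 3, a ratio of 46 (95% counting interval 15.4 to 226). The peptide transporter SLC15A2 (5.05, SE 0.390), ECRG4 (4.92, SE 0.573) and the cytokine receptor subunit CRLF2 (4.47, SE 0.456) followed. The largest falls were UCA1 (-2.37, SE 0.159), KRTAP4-8 (-2.35, SE 0.434), PCDH19 (-2.24, SE 0.401), RIMS1 (-1.88, SE 0.385), GJA5 (-1.53, SE 0.249), SERTAD4 (-1.50, SE 0.117), SERTAD4-AS1 (-1.49, SE 0.235), ANGPTL4 (-1.47, SE 0.098) and RIMS2 (-1.43, SE 0.193). RELA did not pass (-0.09, SE 0.038, adjusted p = 0.0709). PTMS rose by 1.17 on the log2 scale (SE 0.054, adjusted p = 2.52e-13), LAG3 by 2.36 (SE 0.497, adjusted p = 0.000619), MLF2 by 0.23 (SE 0.041) and C1S, 201.4 kb from CD4, by 1.11 (SE 0.176). CD4 neighbours rose in 7 of 13 cases and fell in 2 (camera adjusted p = 0.0448, adjusted p = 0.286 with an estimated correlation), and genes within 500 kb rose in 17 of 42 and fell in 6 (19 and 6 adjusted over the list alone; camera adjusted p = 0.0149, adjusted p = 0.259 with an estimated correlation).

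With p65, interferon response genes rose in 15 of 24 cases and fell in 1 (16 and 1 adjusted over the list alone). IFI44 stood at 1.62 (SE 0.093), OASL at 2.42 (SE 0.145) and ISG20 at 1.69 (SE 0.106), with camera adjusted p = 6.48e-08 (adjusted p = 0.0432 with an estimated correlation). NF-kB targets rose in 10 of 26 cases and fell in 0. TRAF1 stood at 1.71 (SE 0.116) and BIRC3 at 0.72 (SE 0.075), with camera adjusted p = 0.000805 (adjusted p = 0.0432 with an estimated correlation). MHC class I genes rose in 11 of 15 cases. HLA-B stood at 0.91 (SE 0.049) and B2M at 0.49 (SE 0.034), with camera adjusted p = 9.6e-08 (adjusted p = 0.0767 with an estimated correlation). Unfolded protein response genes rose in 16 of 18 cases. HSPA5 stood at 0.49 (SE 0.039) and HERPUD1 at 0.71 (SE 0.062), with camera adjusted p = 6.04e-08 (adjusted p = 0.0767 with an estimated correlation). All 23 DNA replication genes fell. RRM2 stood at -0.63 (SE 0.045), with camera adjusted p = 6.48e-13 (adjusted p = 0.0767 with an estimated correlation). All 20 G2/M genes fell. MKI67 stood at -0.79 (SE 0.067), with camera adjusted p = 7.83e-12 (adjusted p = 0.0767 with an estimated correlation). YAP/TEAD targets fell in 11 of 17 cases and rose in 2. ASAP1 stood at -0.55 (SE 0.041) and CRIM1 at 0.33 (SE 0.035), with camera adjusted p = 0.00354 (adjusted p = 0.206 with an estimated correlation). Coactivator genes fell in 15 of 39 cases and rose in 2. CREBBP stood at -0.43 (SE 0.057), with camera adjusted p = 0.0472 (adjusted p = 0.0909 with an estimated correlation).

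Extracellular matrix genes rose in 8 of 21 cases and fell in 3 (9 and 3 adjusted over the list alone). SPARC stood at 1.03 (SE 0.037) and COL6A1 at 0.90 (SE 0.059), with camera adjusted p = 0.00993 (adjusted p = 0.286 with an estimated correlation). MAPK output genes rose in 13 of 17 cases and fell in 3 (14 and 3 adjusted over the list alone). PHLDA1 stood at 0.46 (SE 0.038) and SPRY2 at 0.61 (SE 0.055), with camera adjusted p = 0.000281 (adjusted p = 0.206 with an estimated correlation). Hypoxia and glycolysis genes rose in 11 of 21 cases and fell in 1 (12 and 1 adjusted over the list alone). NDRG1 stood at 0.97 (SE 0.054), with camera adjusted p = 0.000502 (adjusted p = 0.0767 with an estimated correlation). Cholesterol synthesis genes rose in 7 of 20 cases. INSIG1 stood at 1.09 (SE 0.090), with camera adjusted p = 0.0288 (adjusted p = 0.199 with an estimated correlation). Immediate-early genes rose in 9 of 18 cases and fell in 2 (10 and 2 adjusted over the list alone). IER3 stood at 0.51 (SE 0.053) and FOS at 1.82 (SE 0.415), with camera adjusted p = 0.00993 (adjusted p = 0.369 with an estimated correlation). Melanocyte lineage genes rose in 6 of 17 cases and fell in 2 (7 and 2 adjusted over the list alone). S100B stood at 1.51 (SE 0.122), with camera adjusted p = 0.0411 (adjusted p = 0.286 with an estimated correlation).

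The other lists did not pass with p65. P53 targets rose in 10 of 21 cases and fell in 4 (camera adjusted p = 0.0555), with GDF15 at 0.97 (SE 0.074), and integrated stress response genes rose in 8 of 21 and fell in 4 (0.328), with DDIT4 at 1.90 (SE 0.071). Heat shock genes rose in 5 of 14 cases and fell in 5 (0.746), with a median of -0.07, a mean of 0.28 and an upward camera direction. Genes of dedifferentiated melanoma rose in 6 of 16 cases and fell in 7 (0.705), with a median of -0.09, a mean of 0.09 and a downward camera direction. Mitochondrially encoded genes fell in 4 of 13 cases (8 adjusted over the list alone; 0.0646) and ribosomal protein genes rose in 4 and fell in 4 of 32 (3 and 3 adjusted over the list alone; 0.54). Of the myeloid, epithelial and fibroblast or endothelial markers 1 each rose, CD68 (0.63, SE 0.056), CLDN4 (0.74, SE 0.124) and PDGFRA (1.60, SE 0.428), with camera adjusted p = 0.245, 0.746 and 0.328. IL7R fell (-0.68, SE 0.061).

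With the effective-length offset, 3851 genes passed in place of 5823. MGAT4C was 6.38 with that offset and had 1061 counts against 3 when thinned to the lowest depth, a ratio of 354 (95% counting interval 121 to 1720), RELA passed with the trends on GC content and length removed (-0.21), and C1S (0.84) and PDGFRA (1.33) lost the call with the effective-length offset.

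Across genes, which are not independent replicates, the guide effects with VP64 and p65 had a Pearson correlation of 0.609 (Spearman 0.684) and share no library. Both called 2065 genes higher and 2361 lower, against 541.7 and 642.5 for independent lists, and 13 genes had opposite calls against 1179.9. In both, 181 rose and 28 fell at least 2-fold. RCN3 also rose with p65 (18.5 to 394 CPM) and DNAH9 with VP64 (0.034 to 1.34 CPM), unnamed there.

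**Figure D3:**
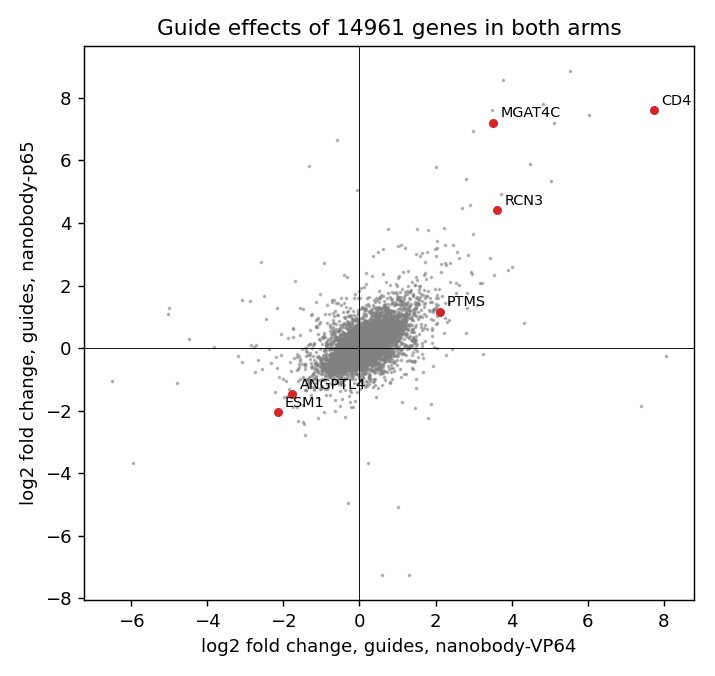
Log2 fold change with guides with the nanobody-p65 (vertical axis) against that with the nanobody-VP64 (horizontal axis), each point 1 of 14961 tested genes. Pearson's r across genes was 0.609, and CD4 lies at 7.75 and 7.60.

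P65 was compared with VP64 in the lines without guides, which asks how the line with p65 differs from that with VP64. Here and in the other comparisons each construct is held by 1 line, so the design does not separate the construct from the line. CD4 did not pass (log2 fold change 0.27, SE 0.163, adjusted p = 0.485), nor did RELA (-0.05, SE 0.038, adjusted p = 0.637). TGFBI, a matrix protein gene (ENSG00000120708.16, chromosome 5, 136028895 to 136063818), fell from 158 ± 1.89 CPM with VP64 to 80.3 ± 4.56 with p65 (-0.97, SE 0.045, adjusted p = 6.97e-12). NGFR, a marker of dedifferentiated melanoma, fell from 125 ± 8.69 to 66.3 ± 6.99 CPM (-0.91, SE 0.084, adjusted p = 7.97e-07), and the immediate-early gene EGR1 from 206 ± 34.2 to 101 ± 15.2 CPM (-1.03, SE 0.188, adjusted p = 0.00267). BCAM rose from 20.1 ± 0.785 to 30.5 ± 3.39 CPM (0.60, SE 0.081, adjusted p = 9.31e-05) and PLTP, a phospholipid transfer protein gene, from 30.2 ± 1.06 to 43.0 ± 1.03 CPM (0.51, SE 0.061, adjusted p = 2.08e-05). Of 14961 genes, 58 rose and 257 fell, and 1 and 9 of these changed at least 2-fold.

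The other named rises were KISS1 (0.85, SE 0.208), DCT (0.77, SE 0.159), MTATP6P1 (0.64, SE 0.141), UNC5B (0.64, SE 0.147), WDR27 (0.62, SE 0.153), UPK3BL1 (0.57, SE 0.135), ZNF678 (0.55, SE 0.138) and ZNF92 (0.54, SE 0.140). The other falls were FOS (-1.77, SE 0.414, adjusted p = 0.0226), RGPD1 (-1.38, SE 0.327), LYPD1 (-1.10, SE 0.109), MPP4 (-1.06, SE 0.172), CDH19 (-0.96, SE 0.211), SORBS2 (-0.93, SE 0.212) and SH3PXD2A-AS1 (-0.93, SE 0.156). MTATP6P1, UPK3BL1 and RGPD1 have near-identical copies in the genome, so their counts are uncertain. Mitochondrial transcripts held 2.40% ± 0.37 of counts with p65 and 1.85% ± 0.093 with VP64 (SD, n = 3).

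Immediate-early genes fell in 6 of 18 cases (8 adjusted over the list alone). JUN stood at -0.52 (SE 0.095) and KLF6 at -0.21 (SE 0.039), with camera adjusted p = 1.79e-07 (adjusted p = 0.149 with an estimated correlation). Extracellular matrix genes fell in 7 of 21 cases (2 rose and 9 fell adjusted over the list alone). THBS1 stood at -0.63 (SE 0.037), with camera adjusted p = 4.94e-06 (adjusted p = 0.149 with an estimated correlation). Genes of dedifferentiated melanoma fell in 5 of 16 cases (1 rose and 5 fell adjusted over the list alone). TNC stood at -0.38 (SE 0.046), with camera adjusted p = 4.94e-06 (adjusted p = 0.0869 with an estimated correlation). Hypoxia and glycolysis genes fell in 4 of 21 cases (5 adjusted over the list alone). SLC2A1 stood at -0.29 (SE 0.047), with camera adjusted p = 0.000117 (adjusted p = 0.0869 with an estimated correlation). Integrated stress response genes fell in 3 of 21 cases (2 rose and 4 fell adjusted over the list alone). SLC7A5 stood at -0.34 (SE 0.035), with camera adjusted p = 0.0128 (adjusted p = 0.149 with an estimated correlation). NF-kB targets fell in 2 of 26 cases (4 adjusted over the list alone), CXCL1 (-0.51, SE 0.075) and IER3 (-0.33, SE 0.053), with camera adjusted p = 0.0133 (adjusted p = 0.108 with an estimated correlation). MAPK output genes fell in 2 of 17 cases (2 rose and 5 fell adjusted over the list alone), including FOSL1 (-0.23, SE 0.037), with camera adjusted p = 0.0276 (adjusted p = 0.648 with an estimated correlation). Mitochondrially encoded genes rose in 7 of 13 cases (12 adjusted over the list alone). MT-CO3 stood at 0.40 (SE 0.066), with camera adjusted p = 1.93e-08 (adjusted p = 0.276 with an estimated correlation). None of 23 DNA replication genes passed, while camera gave an upward shift with a median of 0.06 (adjusted p = 0.0436, adjusted p = 0.683 with an estimated correlation).

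Among lists that camera did not pass here, melanocyte lineage genes rose in 1 and fell in 2 of 17 cases (1 and 4 adjusted over the list alone; median 0.02, mean 0.02 and a downward camera direction), with GPNMB at -0.36 (SE 0.042). YAP/TEAD targets rose in 1 and fell in 3 of 17 (3 and 5 adjusted over the list alone), with CRIM1 at -0.24 (SE 0.035), p53 targets had 1 rise (CCNG1, 0.19, SE 0.044; 1 and 1 adjusted over the list alone) and G2/M genes 1 rise (KIF11, 0.20, SE 0.037). Among the CD4 neighbours, interferon response, MHC class I, unfolded protein response, heat shock, cholesterol synthesis, coactivator, ribosomal protein, marker and 500 kb lists, edgeR passed 0 genes over all genes; adjusted over the list alone, 1 gene each passed in the MHC class I, unfolded protein response, myeloid and 500 kb lists and 2 in the fibroblast and endothelial list.

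With the effective-length offset 109 genes passed in place of 315 (11 higher in place of 58), 545 without a low-count filter (136 higher, 409 lower) and 103 higher with trends on GC content and length removed; leaving out replicate A, B or C of VP64 without guides gave 199, 201 and 185 (22, 23 and 22 higher), and leaving out replicate A or B of p65 without guides gave 185 and 191 (28 and 19 higher). The effective-length offset ended the calls of FOS, KISS1, DCT, MTATP6P1, UNC5B, WDR27, UPK3BL1, ZNF678, ZNF92, RGPD1, MPP4, CDH19, SORBS2, KLF6 and CCNG1, the replicate block those of WDR27, ZNF678 and ZNF92, a fit to the groups compared alone and thinning that of ZNF92, and the removal of trends on GC content and length those of ZNF678, ZNF92, CCNG1 and KIF11; DESeq2 gave KISS1 and RGPD1 no adjusted p (3482 genes in all), with folds no smaller than reported, and leaving out single libraries ended the calls of all these but MPP4, KLF6 and KIF11, FOS among them without replicate A (-1.54) or B (-1.77) of VP64 or replicate B (-1.74) or C (-1.39) of p65.

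P65 was compared with VP64 in the lines with guides, which asks how the line with p65 differs from that with VP64 when the guides are present. CD4 did not pass (log2 fold change 0.12, SE 0.1, adjusted p = 0.556), nor did RELA (0.01, SE 0.039, adjusted p = 0.957). MGAT4C was higher with p65, at 22.4 ± 0.973 against 0.847 ± 0.251 CPM (4.69, SE 0.186, adjusted p = 1.89e-13). The transcription factor TFCP2L1 was higher, at 51.6 ± 4.16 against 14.2 ± 0.0754 CPM (1.86, SE 0.090, adjusted p = 6.09e-12). TGFBI was lower, at 79.8 ± 2.06 against 177 ± 7.25 CPM (-1.15, SE 0.045, adjusted p = 1.89e-13), and PTMS next to CD4 was lower (-1.05, SE 0.053, adjusted p = 1.23e-11). Of 14961 genes, 557 were higher and 628 lower with p65, and 43 and 22 of these differed at least 2-fold.

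The other largest differences toward p65 were ECRG4 (4.66, SE 0.582), SLC15A2 (4.47, SE 0.379), PIGR (3.86, SE 0.252), ESYT3 (3.32, SE 0.415), THEG (2.92, SE 0.496), the transcription factor TFEC (2.29, SE 0.232) and PPFIA2 (1.75, SE 0.313). Toward VP64 they were SLCO4A1-AS1 (-1.76, SE 0.330), FOS (-1.76, SE 0.354), CDH19 (-1.40, SE 0.194), GASK1B (-1.40, SE 0.234), FP565260.2 (-1.39, SE 0.329), MEGF10 (-1.38, SE 0.320), CD96 (-1.31, SE 0.269), LAG3 (-1.25, SE 0.360) and MPP4 (-1.23, SE 0.205).

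CD4 neighbours were lower with p65 in 5 of 13 cases (6 adjusted over the list alone). ENO2 stood at -0.27 (SE 0.044) and P3H3 at -0.32 (SE 0.056), with camera adjusted p = 7.1e-06 (adjusted p = 0.0845 with an estimated correlation). Immediate-early genes were lower in 8 of 18 cases (10 adjusted over the list alone). IER3 stood at -0.64 (SE 0.052) and KLF6 at -0.30 (SE 0.039), with camera adjusted p = 7.1e-06 (adjusted p = 0.177 with an estimated correlation). MAPK output genes were lower in 8 of 17 cases (9 adjusted over the list alone). CCND1 stood at -0.36 (SE 0.038), with camera adjusted p = 0.000181 (adjusted p = 0.183 with an estimated correlation). Hypoxia and glycolysis genes were lower in 6 of 21 cases (1 higher and 7 lower adjusted over the list alone). SLC2A1 stood at -0.34 (SE 0.047), with camera adjusted p = 1.6e-05 (adjusted p = 0.0845 with an estimated correlation). Genes of dedifferentiated melanoma were higher in 1 and lower in 5 of 16 cases (1 and 7 adjusted over the list alone). NGFR stood at -0.92 (SE 0.081), with camera adjusted p = 0.000236 (adjusted p = 0.0845 with an estimated correlation). Integrated stress response genes were higher in 1 and lower in 6 of 21 cases (2 and 8 adjusted over the list alone). SLC7A5 stood at -0.32 (SE 0.035), with camera adjusted p = 0.00071 (adjusted p = 0.0845 with an estimated correlation). Unfolded protein response genes were lower in 3 of 18 cases (6 adjusted over the list alone). HSPA5 stood at -0.19 (SE 0.038), with camera adjusted p = 0.000548 (adjusted p = 0.201 with an estimated correlation). YAP/TEAD targets were higher in 8 of 17 cases and lower in 1 (8 and 2 adjusted over the list alone). ANKRD1 stood at 0.52 (SE 0.083), with camera adjusted p = 0.000638 (adjusted p = 0.177 with an estimated correlation).

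Melanocyte lineage genes were lower in 5 of 17 cases. GPNMB stood at -0.35 (SE 0.042) and ERBB3 at -0.73 (SE 0.099), with camera adjusted p = 0.00155 (adjusted p = 0.177 with an estimated correlation). Cholesterol synthesis genes were lower in 2 of 20 cases (3 adjusted over the list alone), INSIG1 (-0.83, SE 0.080) and STARD4 (-0.38, SE 0.098), with camera adjusted p = 0.00537 (adjusted p = 0.159 with an estimated correlation). Genes within 500 kb of CD4 were lower in 6 of 42 cases (1 higher and 6 lower adjusted over the list alone). GAPDH stood at -0.17 (SE 0.032), with camera adjusted p = 0.00185 (adjusted p = 0.177 with an estimated correlation). Mitochondrially encoded genes were higher in 9 of 13 cases (13 adjusted over the list alone). MT-CO3 stood at 0.33 (SE 0.066), with camera adjusted p = 7.1e-06 (adjusted p = 0.291 with an estimated correlation). Lists that did not pass included the interferon response (2 higher and 3 lower of 24; 2 and 6 adjusted over the list alone; IFIT3 at -0.70, SE 0.104; camera adjusted p = 0.0646) and NF-kB targets (2 and 4 of 26; 4 and 5 adjusted over the list alone; camera adjusted p = 0.233). In the MHC class I list 3 of 15 were higher (3 and 2 adjusted over the list alone), HLA-B among them (0.19, SE 0.049), with a median of 0.03, a mean of -0.02 and an upward camera direction. In the extracellular matrix list 2 were higher and 4 lower of 21 (4 and 7 adjusted over the list alone), and of 21 p53 targets 2 were higher and 3 lower, with GDF15 at -0.44 (SE 0.073).

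The effective-length offset gave 437 genes in place of 1185 and ended the calls of SLC15A2 (2.71), PPFIA2, GASK1B, LAG3, MEGF10, FP565260.2, HLA-B, STARD4 and ERBB3, the removal of trends on GC content and length gave 855 higher and 687 lower, DESeq2 size factors 607 and 587, a fit to the groups compared alone gave 706 and ended those of LAG3 and HLA-B, DESeq2 gave ECRG4 (4.76), ESYT3 (3.35) and THEG (2.94) no adjusted p, as for 1743 genes here, and leaving out replicate B of VP64 with guides or replicate C of p65 with guides gave 681 and 709. ECRG4 was 4.02 without replicate B of VP64 with guides and had 120 counts against 1 without C of it, a ratio of 75.6 (95% counting interval 13.3 to 3010), THEG was 4.04 without C of it and ESYT3 2.42 with the effective-length offset; among the lines with guides, the call of LAG3 was lost without replicate A (-1.25), B (-1.31) or C (-1.20) of VP64 or C of p65 (-0.84), that of HLA-B without A (0.17) or C (0.16) of VP64 or A (0.15) or B (0.16) of p65, that of STARD4 without B of VP64 (-0.27) or C of p65 (-0.29), and those of MEGF10 (-1.09) and FP565260.2 (-1.27) without C of p65.

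**Figure D4:**
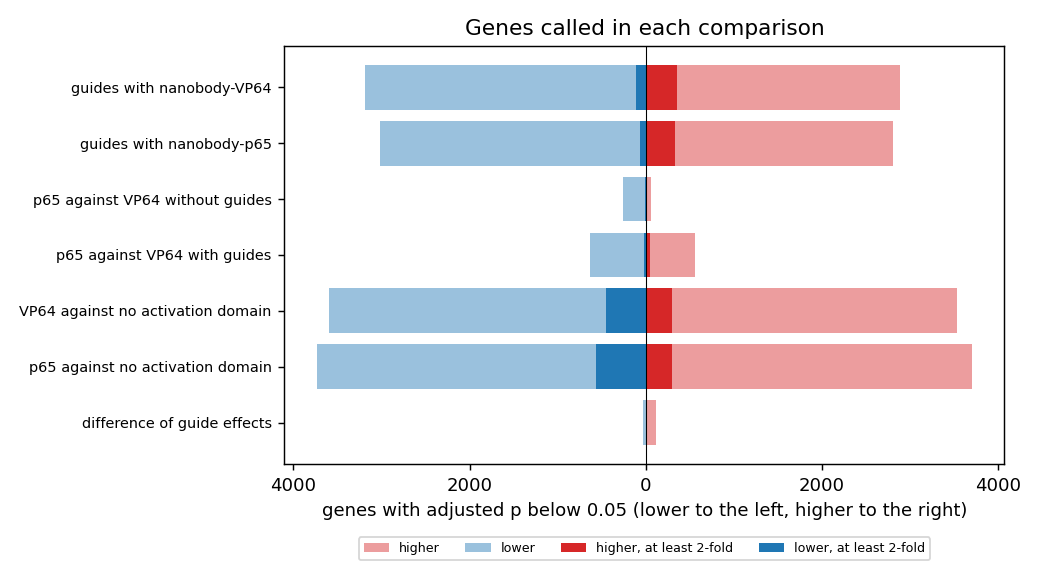
Number of genes past adjusted p of 0.05 in each of the 7 comparisons, higher and lower drawn apart. The counts run from 143 for the difference of guide effects to 7430 for p65 against no activation domain.

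VP64 was compared with no activation domain in lines without guides, which asks how carrying VP64 on both dCas12a and the nanobody changes the cells; the lines also differ in how they were made. CD4 rose from 3.20 ± 1.72 to 8.83 ± 0.541 CPM (log2 fold change 1.5, SE 0.202, adjusted p = 2.43e-06). ANGPTL4 rose from 8.25 ± 0.543 to 59.3 ± 5.56 CPM (2.84, SE 0.112, adjusted p = 2.09e-14). INSIG1, a sterol-responsive protein gene (ENSG00000186480.12, chromosome 7, 155297776 to 155310235), fell from 148 ± 7.60 to 20.9 ± 0.962 CPM (-2.83, SE 0.082, adjusted p = 1.38e-16), and SERPINB2 from 27.3 ± 0.816 to 4.56 ± 0.235 CPM (-2.58, SE 0.109, adjusted p = 6.37e-14). RELA rose slightly (0.18, SE 0.038, adjusted p = 0.000395). Of 14961 genes, 3528 rose and 3598 fell, and 296 and 449 of these changed at least 2-fold.

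The other largest rises were RMRP (4.26, SE 1.006), SFTA1P (3.39, SE 0.420), ILDR2 (3.21, SE 0.187), LIPH (3.16, SE 0.282), ABCC9 (2.93, SE 0.396), SMPDL3B (2.72, SE 0.297), GABRA6 (2.58, SE 0.181), PLEKHA7 (2.47, SE 0.151) and H2BC4 (2.40, SE 0.270). FRG2, which has near-identical copies, had 2 counts against 127, 59.1-fold lower (95% counting interval 16 to 493). The acute-phase gene SAA1 (-3.60, SE 0.312), the calcium-binding protein gene CALB2 (-3.12, SE 0.221), DENND2A (-3.05, SE 0.245), SHISA2 (-2.69, SE 0.400), SIRPB1 (-2.61, SE 0.143), ITGA10 (-2.55, SE 0.331) and the readthrough gene STAG3L5P-PVRIG2P-PILRB (-2.37, SE 0.314) followed.

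NF-kB targets fell in 16 of 26 cases and rose in 0 (17 and 0 adjusted over the list alone). CXCL1 stood at -1.52 (SE 0.066), IER3 at -0.84 (SE 0.052) and CXCL8 at -1.28 (SE 0.084), with camera adjusted p = 4.74e-05 (adjusted p = 0.0284 with an estimated correlation). Integrated stress response genes fell in 13 of 21 cases and rose in 2. DDIT3 stood at -2.24 (SE 0.088) and ATF4 at -0.80 (SE 0.040), with camera adjusted p = 1.99e-05 (adjusted p = 0.0302 with an estimated correlation). Cholesterol synthesis genes fell in 15 of 20 cases and rose in 2 (15 and 3 adjusted over the list alone). STARD4 stood at -1.63 (SE 0.1), with camera adjusted p = 1.2e-05 (adjusted p = 0.0302 with an estimated correlation). Unfolded protein response genes fell in 15 of 18 cases. HSPA5 stood at -1.33 (SE 0.039) and HERPUD1 at -1.78 (SE 0.061), with camera adjusted p = 9.56e-09 (adjusted p = 0.0739 with an estimated correlation). P53 targets rose in 14 of 21 cases and fell in 3. FAS stood at 1.31 (SE 0.074) and MDM2 at 0.71 (SE 0.054), with camera adjusted p = 0.000485 (adjusted p = 0.0739 with an estimated correlation). YAP/TEAD targets rose in 12 of 17 cases (14 adjusted over the list alone). CCN1 stood at 0.78 (SE 0.052) and AMOTL2 at 0.83 (SE 0.057), with camera adjusted p = 1.25e-05 (adjusted p = 0.0906 with an estimated correlation). DNA replication genes fell in 21 of 23 cases. MCM7 stood at -0.79 (SE 0.040), with camera adjusted p = 2.85e-09 (adjusted p = 0.144 with an estimated correlation). G2/M genes fell in 17 of 20 cases. KIF11 stood at -0.72 (SE 0.037), with camera adjusted p = 2.05e-07 (adjusted p = 0.183 with an estimated correlation).

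Ribosomal protein genes fell in 25 of 32 cases (26 adjusted over the list alone). RPL5 stood at -0.33 (SE 0.032), with camera adjusted p = 2.44e-07 (adjusted p = 0.394 with an estimated correlation). Heat shock genes fell in 10 of 14 cases and rose in 1. HSPD1 stood at -0.40 (SE 0.040), with camera adjusted p = 0.00071 (adjusted p = 0.205 with an estimated correlation). Extracellular matrix genes rose in 11 of 21 cases and fell in 4. THBS1 stood at 0.96 (SE 0.037) and COL4A1 at 1.16 (SE 0.067), with camera adjusted p = 0.00527 (adjusted p = 0.312 with an estimated correlation). Immediate-early genes fell in 9 of 18 cases and rose in 2 (9 and 3 adjusted over the list alone). KLF4 stood at -1.77 (SE 0.116), with camera adjusted p = 0.0157 (adjusted p = 0.466 with an estimated correlation). Hypoxia and glycolysis genes fell in 13 of 21 cases and rose in 5. NDRG1 stood at -1.14 (SE 0.052) and P4HA2 at 0.61 (SE 0.036), with camera adjusted p = 0.0189 (adjusted p = 0.183 with an estimated correlation).

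Lists that camera did not pass for VP64 included MAPK output genes (7 rose and 10 fell of 17, camera adjusted p = 0.0568), with DUSP5 at -0.93 (SE 0.051), and myeloid markers (1 rose and 7 fell of 11; 1 and 8 adjusted over the list alone; 0.0555), with CD14 at -1.72 (SE 0.348). Interferon response genes rose in 9 and fell in 3 of 24 (0.115), with ISG15 at 1.22 (SE 0.117), and MHC class I genes rose in 7 and fell in 2 of 15 (8 and 2 adjusted over the list alone; 0.0656), with HLA-B at 0.44 (SE 0.049). Melanocyte lineage genes rose in 3 and fell in 6 of 17 (0.248), and mitochondrially encoded genes rose in 3 of 13 (0.116). Genes of dedifferentiated melanoma rose in 6 and fell in 5 of 16 (0.775), with NGFR at -2.36 (SE 0.082), a median of 0.05, a mean of -0.09 and an upward camera direction. Median, mean and camera direction also differed in sign for CD4 neighbours (0.07, -0.25 and downward; 4 rose and 6 fell of 13), coactivators (-0.01, 0.00 and upward), fibroblast and endothelial markers (-0.32, -0.21 and upward) and genes within 500 kb (-0.04, -0.03 and upward; 14 rose and 12 fell of 42). IL7R rose (1.30, SE 0.062).

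Without replicate C of the line without an activation domain CD4 was 1.08; without replicate B of VP64, RMRP was 2.37 and SAA1 -4.69; without replicate C of VP64, FRG2 had 0 counts against 127, at least 26.6-fold lower (39.1-fold, interval 10.6 to 326, without A or B). With the effective-length offset ILDR2 was 4.19, STAG3L5P-PVRIG2P-PILRB -1.34, and RELA lost the call (0.17).

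P65 was compared with no activation domain in lines without guides, which asks the same of p65 beside VP64. CD4 rose from 3.20 ± 1.72 to 10.6 ± 0.563 CPM (log2 fold change 1.77, SE 0.194, adjusted p = 1.25e-07). NGFR (ENSG00000064300.8, chromosome 17, 49495293 to 49515017) fell from 639 ± 6.31 to 66.3 ± 6.99 CPM (-3.27, SE 0.086, adjusted p = 3.49e-17), and INSIG1 from 148 ± 7.60 to 18.0 ± 1.02 CPM (-3.04, SE 0.083, adjusted p = 3.86e-17). BCAM rose from 4.93 ± 0.587 to 30.5 ± 3.39 CPM (2.63, SE 0.099, adjusted p = 5.98e-15). RELA rose slightly (0.14, SE 0.038, adjusted p = 0.00481). Of 14961 genes, 3700 rose and 3730 fell, and 296 and 568 of these changed at least 2-fold.

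The other largest rises were SFTA1P (3.52, SE 0.414), SMPDL3B (2.96, SE 0.291), ILDR2 (2.92, SE 0.190), ANGPTL4 (2.90, SE 0.111), LIPH (2.74, SE 0.290), PLEKHA7 (2.69, SE 0.148), MATN2 (2.16, SE 0.193) and H4C8 (2.13, SE 0.233). FRG2 had 2 counts against 127, 63-fold lower (95% counting interval 17.1 to 526). ITGA10 (-3.77, SE 0.377), DENND2A (-3.67, SE 0.260), ADAM8 (-3.41, SE 0.5), CALB2 (-3.37, SE 0.225), SAA1 (-3.00, SE 0.290), FOS (-3.00, SE 0.402) and LYPD1 (-2.98, SE 0.096) also fell. Mitochondrial transcripts held 1.65% ± 0.173 of counts in the line without an activation domain, against 2.40% ± 0.37 with p65 (SD, n = 3), and mitochondrially encoded genes rose in 13 of 13 cases, with MT-CO3 at 0.62 (SE 0.066) and camera adjusted p = 0.000175 (adjusted p = 0.387 with an estimated correlation).

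NF-kB targets fell in 19 of 26 cases and rose in 0. CXCL1 stood at -2.04 (SE 0.069), IER3 at -1.18 (SE 0.053) and CXCL8 at -1.54 (SE 0.085), with camera adjusted p = 6.1e-06 (adjusted p = 0.0138 with an estimated correlation). Integrated stress response genes fell in 16 of 21 cases and rose in 2. DDIT3 stood at -2.26 (SE 0.087) and DDIT4 at -2.06 (SE 0.071), with camera adjusted p = 1.43e-06 (adjusted p = 0.0185 with an estimated correlation). Cholesterol synthesis genes fell in 16 of 20 cases and rose in 2. INSIG1 stood at -3.04 (SE 0.083), with camera adjusted p = 4.32e-06 (adjusted p = 0.0196 with an estimated correlation). Unfolded protein response genes fell in 16 of 18 cases. HSPA5 stood at -1.28 (SE 0.039), with camera adjusted p = 3.74e-08 (adjusted p = 0.0648 with an estimated correlation). P53 targets rose in 15 of 21 cases and fell in 3. FAS stood at 1.26 (SE 0.074), with camera adjusted p = 0.000256 (adjusted p = 0.0648 with an estimated correlation). Immediate-early genes fell in 13 of 18 cases (14 adjusted over the list alone). KLF6 stood at -0.79 (SE 0.038) and MYC at -0.59 (SE 0.063), with camera adjusted p = 6.17e-05 (adjusted p = 0.245 with an estimated correlation). MAPK output genes fell in 11 of 17 cases and rose in 4 (11 and 5 adjusted over the list alone). PHLDA1 stood at -0.78 (SE 0.038), with camera adjusted p = 0.00498 (adjusted p = 0.348 with an estimated correlation). Hypoxia and glycolysis genes fell in 14 of 21 cases and rose in 5. NDRG1 stood at -1.44 (SE 0.053), with camera adjusted p = 0.00151 (adjusted p = 0.0923 with an estimated correlation).

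YAP/TEAD targets rose in 11 of 17 cases and fell in 1 (12 and 1 adjusted over the list alone). AMOTL2 stood at 0.85 (SE 0.057), with camera adjusted p = 0.000129 (adjusted p = 0.141 with an estimated correlation). DNA replication genes fell in 19 of 23 cases. MCM7 stood at -0.71 (SE 0.039), with camera adjusted p = 7.58e-08 (adjusted p = 0.186 with an estimated correlation). G2/M genes fell in 18 of 20 cases. CDC20 stood at -0.60 (SE 0.038), with camera adjusted p = 1.43e-06 (adjusted p = 0.219 with an estimated correlation). Ribosomal protein genes fell in 25 of 32 cases. RPL5 stood at -0.33 (SE 0.032), with camera adjusted p = 1.52e-06 (adjusted p = 0.387 with an estimated correlation). Heat shock genes fell in 9 of 14 cases and rose in 1 (11 and 1 adjusted over the list alone). HSPA1A stood at -0.74 (SE 0.053), with camera adjusted p = 0.00366 (adjusted p = 0.294 with an estimated correlation). Myeloid markers fell in 8 of 11 cases and rose in 1 (9 and 1 adjusted over the list alone). FCER1G stood at -1.28 (SE 0.179) and CD68 at 0.42 (SE 0.058), with camera adjusted p = 0.023 (adjusted p = 0.348 with an estimated correlation). Extracellular matrix genes rose in 9 and fell in 5 of 21 (10 and 5 adjusted over the list alone; camera adjusted p = 0.118), with COL4A1 at 0.94 (SE 0.068) and COL5A2 at -2.17 (SE 0.162). Interferon response genes rose in 9 and fell in 3 of 24 (camera adjusted p = 0.171), with ISG15 at 1.23 (SE 0.116). Genes within 500 kb of CD4 rose in 13 and fell in 15 of 42, with a median of 0.01, a mean of -0.06 and a downward camera direction.

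Without replicate C of p65, ADAM8 had 3 counts against 121, 25.3-fold lower (95% counting interval 8.44 to 124), and without replicate B, FRG2 had 0 against 127, at least 28.9-fold lower (39.8-fold, interval 10.8 to 332, without C); without replicate C of the line without an activation domain CD4 was 1.35. With the effective-length offset ADAM8 was -2.68, ILDR2 was 3.85, ERBB3 was -0.67 in place of -1.29, and RELA lost the call (0.26).

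**Figure D5:**
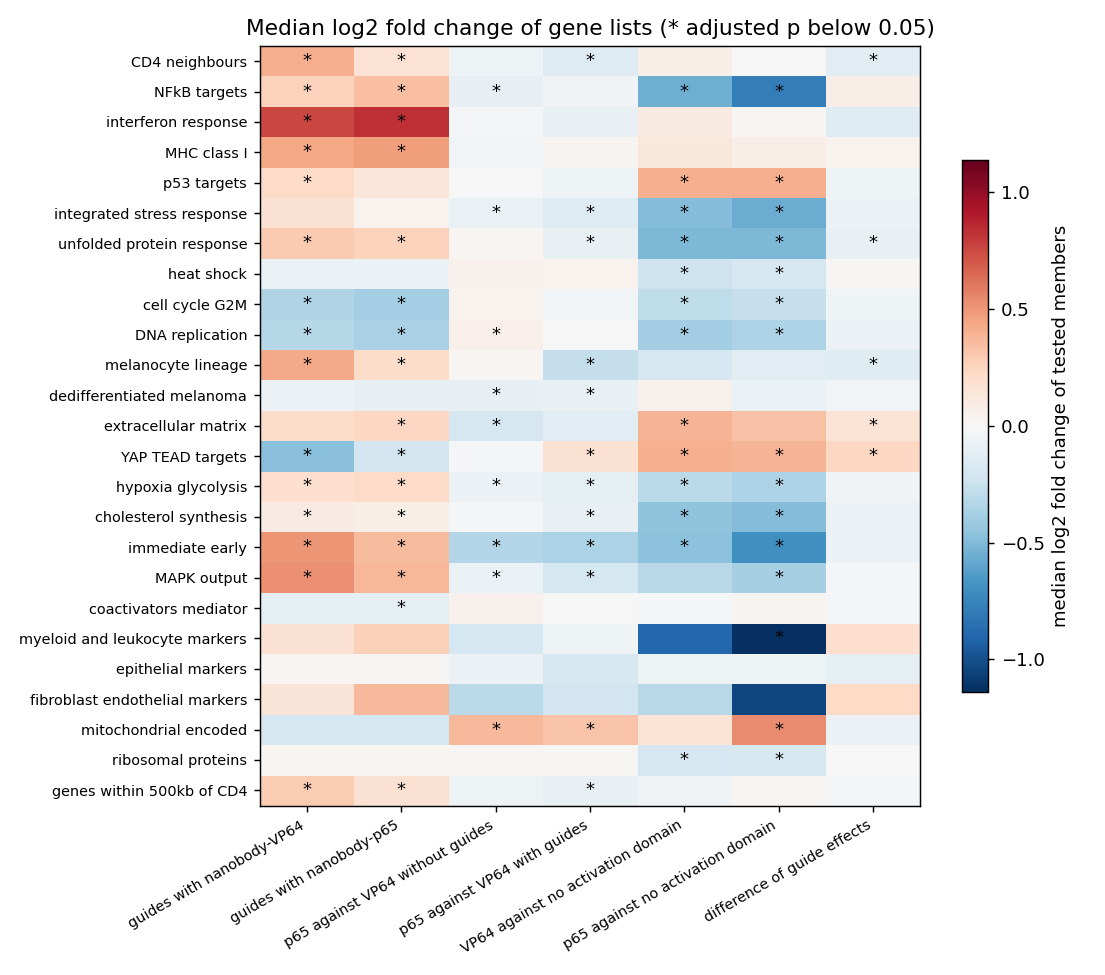
Median log2 fold change of the members of each gene list (colour) in each comparison, with the lists that passed camera marked. Interferon response genes stand at 0.76 and 0.83 with guides, and NF-kB targets at -0.55 and -0.78 against the line without an activation domain.

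Across genes, which are not independent replicates, the effects of VP64 and p65 against the same control libraries had a Pearson correlation of 0.838, a Spearman correlation of 0.866 and a covariance of 0.255. Unchanged simulated groups with shared controls gave a Pearson correlation of 0.497 on average (0.465 to 0.53 in 20 simulations), a Spearman correlation of 0.443 and a covariance of 0.0208, and the 3 controls are too few to be divided between the comparisons. Both called 3014 genes higher and 3006 lower, against 872.5 and 897 for independent lists, and 10 genes had opposite calls; simulated groups shared 0.05 calls on average. The effects of p65 against VP64 without and with guides correlated at 0.166 (Spearman 0.216), with 19 genes called higher in both, 160 lower in both and 7 opposite. SH3PXD2A-AS1, an antisense gene, is uncertain as SLCO4A1-AS1 is, and so is SERTAD4-AS1.

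The difference between the guide effects with p65 and with VP64 was tested directly, which asks for genes whose response to the guides depends on the recruited domain. CD4 did not pass (-0.15, SE 0.191, adjusted p = 0.854), nor did RELA (0.05, SE 0.055, adjusted p = 0.79). PTMS rose less with p65, from 228 ± 18.3 to 512 ± 28.7 CPM, than with VP64, from 246 ± 9 to 1056 ± 27.1 CPM (difference -0.94, SE 0.075, adjusted p = 3.94e-07). SLC15A2 (5.12, SE 0.758, adjusted p = 0.000632), TFEC (2.28, SE 0.440, adjusted p = 0.0089) and SSUH2 (1.69, SE 0.316, adjusted p = 0.00731) also differed toward p65. Of 14961 genes, 115 had a higher and 28 a lower guide effect with p65, and 11 and 1 of these differed at least 2-fold.

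RMRP (6.13, SE 1.467, adjusted p = 0.0442) passed with the uncertainty given above, and DCT (-1.08, SE 0.230), TOX2 (-0.79, SE 0.153), the metallothionein gene MT1X (-0.64, SE 0.117) and INSIG1 (-0.61, SE 0.125) differed toward VP64. YAP/TEAD targets were higher in 4 of 17 cases (8 higher and 1 lower adjusted over the list alone). CRIM1 stood at 0.30 (SE 0.050), with camera adjusted p = 0.00031 (adjusted p = 0.367 with an estimated correlation). CD4 neighbours were lower in 1 of 13 cases (3 adjusted over the list alone), with camera adjusted p = 0.00119 (adjusted p = 0.367 with an estimated correlation), and unfolded protein response genes in 1 of 18 (2 adjusted over the list alone), HSPA5 (-0.24, SE 0.054), with camera adjusted p = 0.00172 (adjusted p = 0.595 with an estimated correlation). Extracellular matrix genes were higher in 3 of 21 cases (9 adjusted over the list alone). THBS1 stood at 0.40 (SE 0.052) and FN1 at 0.77 (SE 0.107), and the list had a median of 0.16 and a mean of -0.02, with camera adjusted p = 0.00542 upward (adjusted p = 0.595 with an estimated correlation). Melanocyte lineage genes were lower in 1 of 17 cases (2 adjusted over the list alone), with camera adjusted p = 0.0481 (adjusted p = 0.595 with an estimated correlation). The dedifferentiated melanoma list differed in sign (median -0.03, mean 0.04, upward). Over all 7 comparisons, the list calls that held with an estimated correlation were the interferon response for the guides with either nanobody, NF-kB targets for the guides with p65, and NF-kB targets, the integrated stress response and cholesterol synthesis for each activation domain against none.

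The count of 143 became 31 with the effective-length offset, 360 without a low-count filter, 247 with DESeq2, which gave 4062 genes no adjusted p, SLC15A2 and TFEC among them with folds no smaller than reported, and 295 with trends on GC content and length removed, and was 95 without replicate B of VP64 without guides and 91 without replicate B of p65 without guides, with the 28 lower ones at 9 and 18 without B of VP64 and C of p65 with guides, at 13, 11 and 11 without B and C of VP64 and B of p65 without guides, at 54 without A of p65 with guides, and at 122, 5, 70, 47 and 17 without a low-count filter, with the effective-length offset, with the trends removed, with DESeq2 and with the groups compared alone. RMRP moved between 4.05 without replicate C of p65 with guides and 6.80 without replicate B of VP64 with guides (4.21 without replicate B of VP64 and 6.74 without replicate A of p65, both without guides), SLC15A2 to 3.82 and SSUH2 to 2.30 with the effective-length offset, an offset that ended the calls of RMRP, SLC15A2, TFEC, SSUH2, DCT, TOX2, MT1X, INSIG1 and HSPA5; the replicate block ended those of RMRP and HSPA5, a fit to the groups compared alone that of RMRP, and leaving out 1 library those of RMRP and HSPA5 (8 of 12 libraries each), DCT (replicate B of VP64 with guides, C of VP64 or B of p65 without), TFEC (B, 2.07, or C, 2.12, of VP64 without guides), SSUH2 (A of VP64 without guides, 1.33) and INSIG1 (C of p65 without guides, -0.56).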

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

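The tests of CD4 in the lines without guides and of the genes next to CD4, the comparisons of the guide effects with each other as an explanation, the removal of trends on GC content and length, and the splits that keep guide status were chosen only after the results were seen; the other splits of the libraries were planned.

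The guide effect differed between the p65 and VP64 arms, tested by an interaction term, in 143 genes. SLC15A2 (difference of log2 fold changes 5.12), TFEC (2.28), SSUH2 (1.69) and RMRP (6.13) differed upward with p65. DCT (-1.08), PTMS (-0.94), TOX2 (-0.79), MT1X (-0.64) and INSIG1 (-0.61) differed downward. The fitted guide effects of RMRP (-5.03 with VP64, 1.10 with p65) and DCT (0.41 and -0.68) had opposite signs. RMRP rests on small RNA levels that vary up to 33.4 CPM within a group, where the short transcript and its 2 overlapping annotated genes limit the value. Of 100 splits of the 12 libraries into the same group sizes, 5 gave as many genes as the real one, itself included, and the highest other split gave 7281. That split set the 6 libraries with guides against the 6 without, and the other 3 had 5 of the 6 libraries with guides on one side. Further splits with 5 of these 6 on one side gave 0 genes. With guide status kept and only the nanobody exchanged, 11 of 100 splits gave as many, the highest other with 1263, and all 10 others had at least 5 of the 6 p65 libraries on one side. Splits with so many genes point to a structure of the samples, here the effects of guides and nanobody, so neither count tells whether chance can be excluded for the 143 genes.

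CD4 had 164 to 245 counts per library in the lines without guides that carry an activation domain, against 28 to 88 in the line without one. Reads or cells carried over from the libraries with guides were tested with other genes raised at least 16-fold by the guides, which would have to be present at the share of CD4 (0.428% to 0.562%). Their summed counts were 9.05 to 46.4 times those needed, but they include the genes' own expression without guides, so carry-over cannot be told apart. The presence of an activation domain may raise CD4 without guides: the lowest log2 fold change against the line without a domain was 1.08 with each replicate left out, and the highest 2.07. The lines also differ in how they were made, which the design does not separate from the domain.

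With guides, 6074 genes differed with VP64 and 5823 with p65. Independent drift of each line is argued against by the correlation of 0.609 across genes between effects that share no library, also with CD4 left out (0.603) and with Spearman's rho (0.684). With the trends of the libraries on GC content and gene length removed, 6295 genes were called with VP64 and 5695 with p65, while the difference of guide effects went from 143 to 295 genes, which argues against these trends as the cause of all the calls. For part of the calls they stay open: 86.1% of the VP64 calls and 78.5% of the p65 calls stayed in the same direction, and the bound written before that test, at least 80% in both arms, was not met with p65. A property shared by both lines with guides, such as the vector or handling of the guide cassette, could also be a source: 4426 genes were called in the same direction in both arms, but the targeting of CD4 would give the same, so these cannot be told apart. Guide binding at other sites was not analysed here.

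Genes next to CD4 rose with guides, PTMS and LAG3 most. Reads of CD4 transcripts counted for neighbours are argued against as the cause for PTMS: its gain per CPM gained by CD4 was 0.321 times as large in the p65 arm as in the VP64 arm (0.307 to 0.347 over the combinations of libraries), while a common share of CD4 reads would give about the same in both. The ratio was 0.371 (0.33 to 0.419) for the 9 neighbours called higher in either arm, where PTMS held 74.9% of the gain with VP64. For the 8 others it was 0.522 (0.385 to 0.877), so there such reads stay open. Spread of activation along the chromosome stays open: over 42 genes within 500 kb the rank correlation of log2 fold change with distance was -0.1 with VP64 (permutation p = 0.53) and 0.083 with p65 (permutation p = 0.599). All 4 tested genes within 50 kb rose in both arms, with medians of 1.27 and 0.70.

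For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05, and in each only 1 split, the real one, gave as many genes. The real and highest other counts were 6074 and 0 for guides with VP64, 5823 and 0 for guides with p65, 315 and 0 for p65 against VP64 without guides, and 1185 and 2 for the same with guides. They were 7126 and 0 for VP64 and 7430 and 0 for p65 against no activation domain.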

How the results depend on the processing

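The removal of trends on GC content and length and the thinning to the lowest depth were chosen only after the result was seen; the other alternatives were fixed earlier. Causes were not tested where none is given.

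The CD4 calls with guides and against the line without an activation domain were made in every alternative run. With 1 replicate left out CD4 ran from 7.72 to 7.81 and from 7.56 to 7.64 with guides (VP64, p65), from 1.08 to 1.80 and from 1.35 to 2.07 against no activation domain, from 0.23 to 0.32 and from 0.09 to 0.17 for p65 against VP64 without and with guides, and from -0.20 to -0.10 for the difference of guide effects.

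With the effective-length offset, counts fell to 3851 for guides with p65, 109 (3 at least 2-fold) for p65 against VP64 without guides, 437 (39) with guides and 31 (5) for the difference of guide effects, and 65.6% and 63.8% of the guide calls were kept. Without a low-count filter, p65 against VP64 gave 545 genes (74 at least 2-fold) without guides and 127 at least 2-fold with guides, and the difference of guide effects 360 (74). A mean of at least 1 CPM gave 40 at least 2-fold for p65 against VP64 with guides. DESeq2 gave 4 and 42 at least 2-fold for p65 against VP64 without and with guides and 247 for the difference of guide effects. A fit to only the groups compared gave 706 for p65 against VP64 with guides. The GC and length offset gave 295 (20 at least 2-fold) for the difference of guide effects.

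With the replicate letter as a block the counts were 5917, 5667, 275, 1048, 7000, 7308 and 128 in the order of the comparisons.

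With 1 replicate left out the counts ran from 5129 to 5737 (guides with VP64), 4891 to 5819 (guides with p65), 185 to 301 (p65 against VP64 without guides), 681 to 1129 (with guides), 6293 to 6394 (VP64 against no domain), 6648 to 6921 (p65 against no domain) and 91 to 176 (difference of guide effects). For p65 against VP64 without guides the lowest were 199, 201 and 185 without replicates A, B and C of VP64 and 185 and 191 without replicates A and B of p65, and 6 genes passed at least 2-fold without replicate C of p65. With guides they were 681 without replicate B of VP64 and 709 without replicate C of p65. The difference of guide effects gave 95 without replicate B of VP64 and 91 without replicate B of p65, both without guides.

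List tests passed 1, 2, 0, 0, 3, 3 and 0 lists with an estimated correlation in place of 15, 16, 9, 12, 13, 15 and 5. Fry passed 20 for VP64 against no activation domain and 2 for the difference of guide effects. For the latter, 8 lists passed with a mean of at least 1 CPM and 9 without replicate C of VP64 with guides or replicate A of VP64 without guides. The agreement of the guide effects was 0.883 on genes with a mean of at least 10 CPM and 0.684 with Spearman's rho, and that of the activation domain effects 0.947 on such genes.

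RELA, which was not called in these comparisons, changed sign for p65 against VP64 with guides (0.0064 as reported, -0.00068 with a mean of at least 1 CPM, -0.0092 without replicate C of VP64 with guides, -0.0050 without replicate A of p65 with guides; with 1 replicate left out, 0.018 at most, without replicate A of VP64 with guides), and with the effective-length offset for p65 against VP64 without guides (0.10) and the difference of guide effects (-0.028).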

Other observations

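The comparison of guide and activation domain effects with no shared library was chosen only after the result was seen.

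The guide effects ran in part against the activation domain effects. Across genes, the guide effect with VP64 and the effect of p65 against no domain, which share no library, correlated at -0.163 (Spearman -0.167), with 2367 genes called in opposite directions against 1508 for independent lists, 678 higher in both against 714.5 and 748 lower in both against 794.1. The guide effect with p65 and the effect of VP64 against no domain correlated at -0.069 (Spearman -0.052), with 1846 opposite against 1386.3, but there the calls in the same direction were also more than independent lists give (818 higher against 661.5 and 855 lower against 725.8), so this pair shows it only weakly. INSIG1, DDIT4 and HSPA5 fell with a domain and rose with guides, and ANGPTL4 did the reverse. The DNA replication and G2/M lists fell both times. The 2 lines with a domain and no guides may in part differ from the other 3 in culture state, which was not tested. The correlation of 0.609 between the guide effects argues against independent drift as a full account.

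Mitochondrial transcripts held 2.03% to 2.80% of counts in the 6 p65 libraries and 1.47% to 1.95% in the 9 others. RN7SK, RMRP and RPPH1 varied together in single libraries, RN7SK from 2.79 to 40.4 CPM among the VP64 libraries without guides and from 2.49 to 25.5 among the p65 libraries with guides. The fitted changes of RMRP and RPPH1 rest on such libraries (RMRP -3.12 without replicate B of VP64 without guides in place of -5.03).

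CD4 had 28 counts (1.22 CPM) in replicate C of the line without an activation domain, against 76 and 88 in the other 2. Without that library the fold changes of CD4 were 1.08 and 1.35 on the log2 scale in place of 1.5 and 1.77.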
